A study of Caenorhabditis briggsae with 9 samples.

How the data were processed

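Whole-animal RNA of synchronized L3 larvae of Caenorhabditis briggsae was measured by RNA sequencing in 9 libraries, 3 from each of 3 strains. The strains were the wild-type isolate AF16, a strain with allele gu163 of Cbr-spr-4 and another with allele gu167 of Cbr-htz-1. Per the labels' protocols, animals were grown at 20 degrees, staged under Nomarski optics and harvested shortly before the vulval precursor cells divide. RNA was depleted of ribosomal RNA and sequenced as single reads on an Illumina HiSeq 2000 instrument. The labels call the replicates independent and biological.

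The deposited values are raw read counts per gene, 1 column per library, with no normalization by the authors. A table of the whole series held the same counts in 9 of 9 columns. The submitters' processing notes name Trim Galore, FastQC, STAR and DESeq without versions or roles. The genome build, gene annotation, counting tool and strand setting are not given in the sources used here. Reads from a gene and from an overlapping or antisense gene therefore cannot be told apart. Levels of near-identical members of multigene families, such as collagens and C-type lectins, are uncertain where reads could be split between copies. Each library held counts for 22922 gene identifiers, with 8294524 to 14095189 counts in total. Symbols were matched by locus tag to a reference gene table of assembly CB4, which was used only for names and for which genes neighbour each other. It matched 22727 identifiers and left 195 unmatched, and 4924 of the genes tested (39.4%) carried a symbol.

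Counts were tested with edgeR 4.0.16 in R 4.3.3, with TMM normalization, its expression filter with a minimum count of 10, robust quasi-likelihood fits and F tests. All 9 libraries entered 1 fit with 3 groups, which left 12507 genes. The p-values were adjusted by the Benjamini-Hochberg method over all genes tested, and adjusted p under 0.05 was called changed. The labels print the submitters' FDR as 0.05%, which could mean 0.05 or 0.0005. It was read as 0.05, and 0.0005 was run as an alternative. Each mutant was compared with AF16, and gu167 was compared with gu163. The standard error of a log2 fold change was taken from the F statistic. Levels are given as CPM, counts relative to the TMM-scaled library total, as mean ± SD of 3 libraries, and fold changes as log2 ± SE. Where the lower group held 1 to 3 counts in all, the ratio of counts is given with its exact 95% interval. Such intervals cover counting error only. A level of 3 counts lies between 0.189 and 0.391 CPM in these libraries. Single genes of the strains were also compared by exact two-sided permutation tests of 3 libraries against 3, whose smallest p is 0.1.

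Before the data were examined, the tests, the alternatives, 27 gene lists and the rule for named genes were fixed. The rule took the strains' own genes and Cbr-lin-3. For each mutant against AF16 it took the 6 largest rises and the 6 largest falls among called genes with a symbol, a mean of at least 5 CPM in the higher group and no overlap between the libraries of the strains. It also took the 2 largest each way by the same criteria with or without a symbol. From every list with a passing test or at least 3 called members it took the 3 members with the smallest adjusted p. From the EGF and Ras, Notch, Wnt and synMuv lists it took up to 5 called members each. It took up to 5 genes with a symbol that rose in both mutants and up to 5 that fell in both, ranked by the larger adjusted p, up to 5 that moved in opposite directions, and the 3 largest changes each way between the mutants. Genes named outside the rule are said to have been chosen after their values were seen.

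Lists were built from C. elegans gene families and matched by symbol. They were tested with camera in limma 3.58.1 on voom-weighted log2 CPM, two-sided, with a preset inter-gene correlation of 0.01 and Benjamini-Hochberg adjustment over the 25 lists with at least 5 measured members. Camera with an estimated correlation and fry were alternatives. With an estimated correlation, the germline list held in each mutant against AF16 and no other list call held. Member counts are given over all genes and adjusted over the list alone.

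The steps were tested on simulated counts of 12507 genes with 200 genes changed by known folds. For gu163 against AF16, 36% of the 2-fold and 88% of the 4-fold changes were recovered, with 4 false calls. For gu167 against AF16 the recovered shares were 29% and 86%, with 9 false calls. For gu167 against gu163 they were 38% and 84%, with 5 false calls. False calls made up 3.1%, 7.3% and 3.9% of the calls in these 3 comparisons. Each gene was drawn on its own, so deviations of whole libraries were not simulated. Replicate pairs differed by far more than sampling noise, with chi-square per degree of freedom of 17.3 to 79.2, so no library was counted as a copy of another. Alternatives were DESeq2 1.42.0, limma-voom, RLE and upper-quartile normalization, other filters on low counts, 2-group fits, stricter thresholds, replicate number as a block and leaving out each library in turn. Leaving out AF16 replicate 3 and gu167 replicate 3 together was added after the data were seen, because these libraries stood apart. RLE or upper-quartile scaling moved the median of all genes by at most 0.07 on the log2 scale.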

Results

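RNA from whole C. briggsae L3 larvae was sequenced in 3 strains with 3 libraries each, to ask which transcripts differ in mutants of Cbr-spr-4 (gu163, also named Cbr-ivp-1) and Cbr-htz-1 (gu167, also named Cbr-ivp-2) when vulval precursor cells are most responsive to the EGF-like signal Cbr-lin-3. Total counts were 9627966, 12062124 and 10654323 in AF16, 8722861, 10907908 and 11657042 in gu163, and 12451179, 14095189 and 8294524 in gu167. Each of the 9 libraries correlated best with a library of its own strain. The first principal component (40.9% of variance) separated gu163 from the other strains. The second (26.6%) placed AF16 replicate 3 at 66.3, above the other AF16 libraries, of which replicate 1 lay at 11.7, and gu167 replicate 3 at -45.8. The TMM factors of these 2 libraries, 0.746 and 1.20, were the lowest and the highest.

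**Figure D1:**
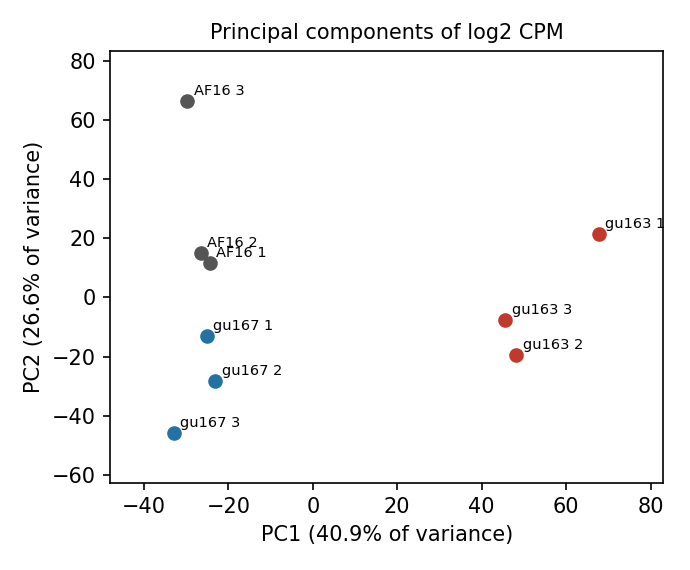
Principal components of log2 CPM over 12507 genes, with 1 point per library coloured by strain; the x axis is the first component (40.9% of variance) and the y axis the second (26.6%). The 3 gu163 libraries lie at 45.6 to 67.8 on the first component, and AF16 replicate 3 lies at 66.3 on the second.

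Cbr-spr-4 (CBG11849), whose C. elegans counterpart encodes a zinc-finger protein found as a suppressor of presenilin mutations, was measured at 88.0, 118 and 120.0 CPM in AF16, 251, 207 and 249 CPM in gu163, and 152, 156 and 144 CPM in gu167. Its transcript was 2.17-fold higher in gu163 than in AF16 (log2 fold change 1.12 ± 0.16, n = 3 per strain, edgeR adjusted p = 0.00232). Its level in gu167 did not pass against AF16 (0.47 ± 0.16, adjusted p = 0.201). Cbr-htz-1 (CBG01691), the gene of the histone variant H2A.Z, was measured at 60.6, 59.9 and 78.7 CPM in AF16, 63.8, 49.7 and 53.2 CPM in gu163, and 61.0, 62.8 and 57.5 CPM in gu167. Its log2 fold changes of -0.26 ± 0.15 in gu163 and -0.13 ± 0.15 in gu167 did not pass (adjusted p = 0.342 and 0.689). The type of either allele is not given in the sources used here, so the transcript levels do not show whether the strains are as labelled.

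Cbr-lin-3 (CBG05996), the EGF-like inductive signal of the vulva, rose from 0.574 ± 0.272 CPM in AF16 to 3.15 ± 0.580 CPM in gu163 and 2.43 ± 0.419 CPM in gu167 (n = 3). The log2 fold change was 2.49 ± 0.40 in gu163 (edgeR adjusted p = 0.00385) and 2.12 ± 0.40 in gu167 (adjusted p = 0.0221). The mutants did not differ by the direct test (-0.37 ± 0.33, adjusted p = 0.502). Counts were low, at 7, 3 and 6 in the AF16 libraries and 21 to 46 in the mutant libraries. The call in gu167 was lost without AF16 replicate 2 (adjusted p = 0.0609), gu167 replicate 2 (0.102) or gu167 replicate 3 (0.0635), with only AF16 and gu167 in the fit (0.0698), and without AF16 replicate 3 and gu167 replicate 3 together (0.0599). Exact two-sided permutation tests of Cbr-lin-3 gave p = 0.1 for each mutant, the smallest value 3 libraries against 3 allow. Whole-animal RNA does not show in which tissue Cbr-lin-3 changed. A difference in developmental time between the strains was not separated from genotype for this gene.

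**Figure D2:**
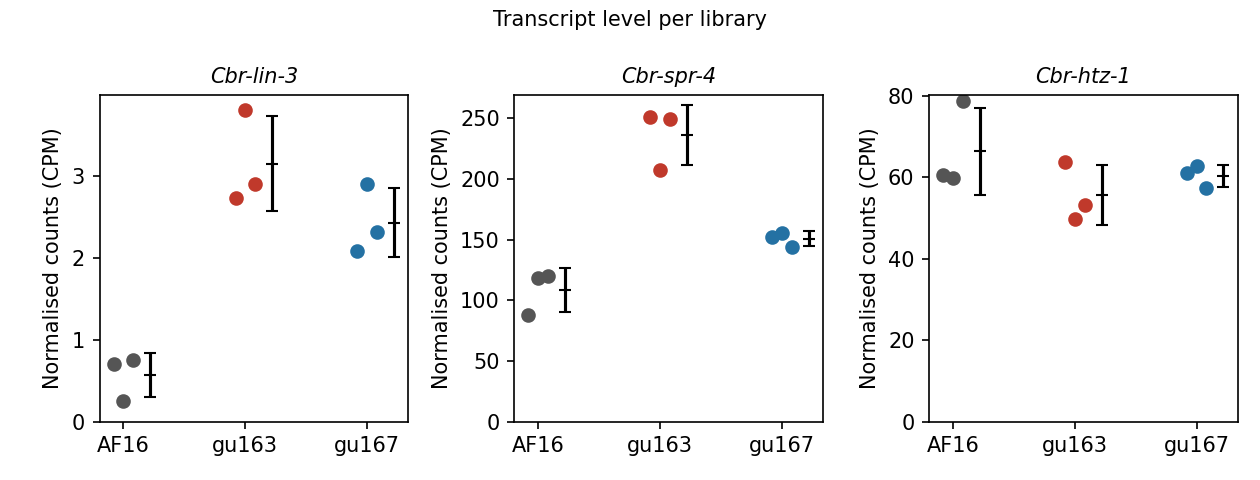
Level of Cbr-lin-3, Cbr-spr-4 and Cbr-htz-1 in CPM (y axis, from 0) for each strain (x axis); points are libraries, and the bar beside them is the mean ± SD of 3 libraries. Cbr-lin-3 averages 0.574 CPM in AF16, 3.15 CPM in gu163 and 2.43 CPM in gu167.

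In gu163 larvae, genes of the germline, sperm, small RNA pathways and DNA replication rose against AF16. Among 50 measured germline and P granule genes, 23 rose and 1 fell (26 and 2 adjusted over the list alone; camera adjusted p = 8.42e-09, and adjusted p = 0.0203 with an estimated correlation). Cbr-puf-8, which encodes a Pumilio-family RNA-binding protein, rose 12.1-fold (log2 3.59 ± 0.21, edgeR adjusted p = 9.32e-06). Cbr-egg-3 and Cbr-egg-4, genes of egg activation proteins, rose 26.4-fold (log2 4.72 ± 0.35) and 7.99-fold. Chosen after their values were seen, the meiotic chromosome axis genes Cbr-htp-3 and Cbr-him-3 rose by 2.11 ± 0.29 and 2.43 ± 0.24, and the member that fell was Cbr-puf-12 (-0.54 ± 0.14), whose call was lost in 6 of 6 fits without 1 library (adjusted p up to 0.144). Of 4 yolk genes, too few to test as a list, 1 rose, the oocyte yolk receptor gene Cbr-rme-2 (3.90 ± 0.26, chosen after its value was seen). The yolk protein genes Cbr-vit-2 and Cbr-vit-4 summed to 0.521, 6.38 and 0.805 CPM in the gu163 libraries and 0.504, 0.348 and 6.17 CPM in AF16.

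Of 7 sperm genes, 4 rose and none fell (4 and 0 adjusted over the list alone; camera adjusted p = 0.0155, and adjusted p = 0.160 with an estimated correlation). Cbr-spe-6, which encodes a sperm kinase, rose by log2 2.66 ± 0.34, and Cbr-spe-27, needed for sperm activation, by 4.91 ± 0.69. The TRP channel gene Cbr-spe-41 had 3 counts over the AF16 libraries and a ratio of 61.8 (95% interval 20.8 to 302.2). The sperm call was lost without AF16 replicate 3 (adjusted p = 0.0551). Of 30 small RNA pathway genes, 7 rose (9 adjusted over the list alone; camera adjusted p = 0.000114, and adjusted p = 0.159 with an estimated correlation). The Argonaute gene Cbr-sago-2 rose by 1.43 ± 0.11, the Piwi gene Cbr-prg-1 by 1.71 ± 0.21 and the nucleotidyltransferase gene Cbr-mut-2 by 3.24 ± 0.41. Of 47 DNA replication and cell cycle genes, 14 rose (19 adjusted over the list alone; camera adjusted p = 1.69e-07, and adjusted p = 0.101 with an estimated correlation), among them the origin recognition gene Cbr-orc-3 (1.08 ± 0.15), the replicative helicase gene Cbr-mcm-6 (0.71 ± 0.12) and Cbr-cdk-2 (1.22 ± 0.21). Without gu163 replicate 1, 2 or 3 the count of 14 was 9, 8 and 9.

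Cuticle collagens gave the largest rises in gu163. Of 118 measured members, 24 rose and 2 fell (26 and 3 adjusted over the list alone; camera adjusted p = 0.000114, and adjusted p = 0.764 with an estimated correlation). Cbr-col-158 rose from 0.624 ± 0.772 to 465 ± 566 CPM (log2 9.67 ± 1.24, edgeR adjusted p = 0.00118), with 8554, 2521 and 913 counts in the gu163 libraries. Cbr-col-36 rose by 7.87 ± 0.96 and Cbr-col-71 by 3.84 ± 0.37. Cbr-col-114, Cbr-col-102 and Cbr-col-45 rose by 8.72 ± 1.33, 8.69 ± 1.53 and 8.64 ± 1.33 from 5 or 6 counts over the AF16 libraries. By limma-voom their calls were lost (adjusted p = 0.109, 0.198 and 0.133), as was that of Cbr-col-163 (0.127). The calls of Cbr-col-114 (0.0509), Cbr-col-102 (0.0746) and Cbr-col-163 (0.0520) were lost without AF16 replicate 3 and gu167 replicate 3 together, and with no filter on low counts that of Cbr-col-102 (0.0543). Cbr-col-163 had 3 counts over the AF16 libraries and a ratio of 522 (95% interval 178 to 2534). Cbr-col-85 also rose, by log2 6.89 to 11.02 in the fits without 1 library, and its call was lost without AF16 replicate 3 (adjusted p = 0.0649). That call was also lost by limma-voom (0.135), with no filter on low counts (0.0704) and without AF16 replicate 3 and gu167 replicate 3 together (0.133). Cbr-col-39 fell by 1.69 on the log2 scale (SE 0.37), a call lost without gu163 replicate 2 (adjusted p = 0.0541), and the other member that fell, Cbr-col-146, was chosen after its value was seen (-1.12, lost in 5 of 6 fits without 1 library, adjusted p up to 0.133). The mean log2 change of the list relative to other genes was 1.26, and 0.79 without gu163 replicate 1 (camera adjusted p = 0.0433). The mean deviation of the collagen list from the mean of all libraries was 1.84 in gu163 replicate 1 and 0.44 and 0.52 in the other gu163 libraries. Without AF16 replicate 3 and gu167 replicate 3 together, 11 collagens rose. The 2 that fell were 0 without gu163 replicate 2, and 1 without AF16 replicate 3, gu163 replicate 1 or gu163 replicate 3.

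Among 54 hedgehog-related and patched-related genes, 4 rose and 2 fell in gu163 (4 and 2 adjusted over the list alone; camera adjusted p = 0.0411, and adjusted p = 0.764 with an estimated correlation). Cbr-grl-3 and Cbr-grd-7, genes of hedgehog-like secreted proteins, rose by log2 6.08 ± 0.79 and 3.67 ± 0.64, and the patched-related Cbr-ptr-19 by 2.33 ± 0.42. The list's call was lost without AF16 replicate 2 (adjusted p = 0.202), AF16 replicate 3 (0.0551) or gu163 replicate 1 (0.287), and the mean relative to other genes, 0.42 with all libraries, was 0.69 without AF16 replicate 1 and 0.75 without gu163 replicate 3. The counts were 8 and 1 without AF16 replicate 1, 9 and 1 without gu163 replicate 3, and 4 and 0 without AF16 replicate 3, gu163 replicate 1 or gu163 replicate 2. They were 3 and 0 without AF16 replicate 3 and gu167 replicate 3 together. Of 76 innate immunity genes, 18 rose and 1 fell (25 and 3 adjusted over the list alone; camera adjusted p = 0.000124, and adjusted p = 0.160 with an estimated correlation). The C-type lectin genes Cbr-clec-147, Cbr-clec-86 and Cbr-clec-78 rose by 6.89 ± 0.44, 3.64 ± 0.25 and 6.20 ± 0.60, whereas Cbr-clec-186 fell by 1.83 (SE 0.32). The count that fell was 2 without gu163 replicate 2, and 2 without AF16 replicate 3 and gu167 replicate 3 together.

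Other lists were lower in gu163 than the remaining genes by camera while few members were called. The 78 ribosomal protein genes had a median log2 fold change of -0.55 (camera adjusted p = 8.71e-11, and adjusted p = 0.764 with an estimated correlation), with 1 member higher and 1 lower (0 and 0 adjusted over the list alone). These were Cbr-rpl-11.1 (1.38 ± 0.37) and Cbr-rpl-24.2 (-0.53 ± 0.12), whose calls were lost in 6 and 4 of the 6 fits that left out 1 library (adjusted p up to 0.128 and 0.0912). The mean deviation of the ribosomal list was -0.06, 0.20 and 0.83 in the AF16 libraries and 0.14, -0.39 and -0.27 in gu163, and its mean change relative to other genes moved from -0.65 to -0.37 without AF16 replicate 3 (camera adjusted p = 0.000319). The 33 respiratory chain genes had a median of -0.44 (camera adjusted p = 0.000111, and adjusted p = 0.764 with an estimated correlation), and edgeR called Cbr-nduf-2.2 of complex I (1.72 ± 0.20) and Cbr-sdha-2 of complex II (1.13 ± 0.20) higher and 0 members lower (2 and 0 adjusted over the list alone). At an unadjusted p under 0.05, 12 members were lower and 3 higher, and DESeq2 called 1 lower and 2 higher. The ribosomal, neuronal and nuclear hormone receptor lists had 3, 7 and 10 lower and 1, 3 and 0 higher genes at an unadjusted p under 0.05, and DESeq2 called 1, 2 and 2 lower. For 57 neuronal genes the median was -0.26 (camera adjusted p = 0.0351, and adjusted p = 0.764 with an estimated correlation), while the neuropeptide gene Cbr-flp-1 (2.89 ± 0.45) and the tyrosine hydroxylase gene Cbr-cat-2 (2.14 ± 0.41) rose. The GTP cyclohydrolase gene Cbr-cat-4 fell by 0.80 (SE 0.17), lost without gu163 replicate 2 or 3 (adjusted p up to 0.0670), and the neuronal list call was lost without AF16 replicate 3 (0.749) or gu163 replicate 2 (0.478), its mean relative to other genes moving from -0.24 to -0.38 without AF16 replicate 1. Of the neuronal genes 2 rose and 1 fell (2 and 1 adjusted over the list alone), and the counts were 2 and 2 without AF16 replicate 1, 2 and 3 without AF16 replicate 2, and 2 and 0 without gu163 replicate 2 or 3. The median of 118 nuclear hormone receptor genes was -0.14 (camera adjusted p = 0.0411, and adjusted p = 0.764 with an estimated correlation), a call lost without AF16 replicate 1 (0.212) or gu163 replicate 1 (0.492). Its only called member was Cbr-nhr-45 (-0.92), lost in 5 of 6 fits without 1 library (adjusted p up to 0.117).

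Single genes of other lists also changed in gu163. The Notch receptor gene Cbr-glp-1 rose by log2 1.49 ± 0.18 and the Notch ligand gene Cbr-apx-1 by 2.17 ± 0.40 among 22 Notch signalling genes, of which 3 rose (4 higher and 2 lower adjusted over the list alone). The other was the ligand gene Cbr-dsl-3 (1.19 ± 0.32), whose call was lost in 6 of 6 fits without 1 library (adjusted p up to 0.138). Cbr-lin-7, which in C. elegans helps localise the EGF receptor, fell by 0.87 (SE 0.14) and was, with Cbr-lin-3, 1 of 2 called genes among 26 of EGF and Ras signalling (1 and 1 adjusted over the list alone). Of 29 Wnt signalling and vulval Hox genes, the Frizzled gene Cbr-mom-5 (1.01 ± 0.25) and the beta-catenin gene Cbr-sys-1 (0.83 ± 0.22) rose, each call lost in 5 of 6 fits without 1 library (adjusted p up to 0.111 and 0.146), and 0 rose and 0 fell adjusted over the list alone. Among 133 xenobiotic metabolism genes 11 rose and 8 fell (11 and 9 adjusted over the list alone). Cbr-cyp-31A3, a cytochrome P450 of eggshell formation, rose by 4.42 ± 0.28, and the P-glycoprotein gene Cbr-pgp-9 fell by 1.56 (SE 0.19). The 8 that fell became 4 without AF16 replicate 2, 3 without AF16 replicate 1, gu163 replicate 1 or gu163 replicate 2, and 1 without gu163 replicate 3. Of 19 heat shock genes, Cbr-hsp-70 rose (3.10 ± 0.36) and the mitochondrial chaperone gene Cbr-hsp-6 fell by 1.27 (SE 0.24), among 2 that rose and 2 that fell (3 and 2 adjusted over the list alone). The counts were 1 and 2 without AF16 replicate 1, 2 and 1 without gu163 replicate 1, and 1 and 1 without AF16 replicate 2, gu163 replicate 2 or gu163 replicate 3. Among well-measured called genes with or without a symbol, the largest falls were those of CBG13822 (-4.20 ± 0.27) and CBG12124 (-2.80 ± 0.46). Among those with a symbol, the largest falls were those of the cytochrome P450 gene Cbr-cyp-14A1 (-2.75 ± 0.59, lost without any 1 gu163 library, adjusted p up to 0.0615) and Cbr-ddo-1 (-1.98 ± 0.27). Calls also ended with only AF16 and gu163 in the fit for Cbr-mom-5, Cbr-sys-1, Cbr-rpl-24.2 and Cbr-nhr-45 (adjusted p from 0.0658 to 0.104), and with no filter on low counts for Cbr-dsl-3, Cbr-rpl-24.2 and Cbr-rpl-11.1 (0.0561 to 0.0873). They ended by limma-voom for Cbr-cyp-14A1, Cbr-dsl-3 and Cbr-nhr-45 (0.0511 to 0.0862), and without AF16 replicate 3 and gu167 replicate 3 together for Cbr-dsl-3, Cbr-sys-1, Cbr-rpl-24.2 and Cbr-nhr-45 (0.0509 to 0.111).

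Of 40 muscle genes 2 rose in gu163, of 44 chemoreceptor genes 2, of 28 intestine genes 1, of 33 proteasome genes 1, and of 10 presenilin suppressor and CoREST genes 1, Cbr-spr-4 itself (1, 1, 0, 0 and 1 adjusted over the list alone). Chosen after their values were seen, the others were the muscle genes Cbr-tni-4 (log2 1.57) and Cbr-myo-5 (adjusted p = 0.0488), the chemoreceptor genes Cbr-srsx-25 (3.67) and Cbr-srh-25 (3.11), the intestinal Cbr-cpr-1 (1.79) and the proteasomal Cbr-rpn-6.2 (1.88). The call of Cbr-srh-25 passed in 6 of 6 fits without 1 library, and the calls of the other 5 genes were each lost in 4 or 5 of 6 (adjusted p up to 0.160). The median lay below 0 and the mean above it for the chemoreceptor, intestine, presenilin and heat shock lists, of which camera placed the intestine list lower and the other lists higher, with none past the threshold. The edgeR test called 0 of 26 synMuv, DREAM and NuRD genes, 0 of 18 H2A.Z deposition genes, 0 of 30 molting genes, 0 of 18 heterochronic genes and 0 of 4 histone genes. Adjusted over the list alone 0 genes passed in each. At an unadjusted p under 0.05 these lists had 3, 2, 7, 1 and 0 genes, and DESeq2 called 1, 0, 1, 1 and 0. In all, 795 genes rose and 368 fell in gu163 among 12507 tested (1163 called, 2955 at an unadjusted p under 0.05). The total was 772 without gu163 replicate 2 and 654 without gu163 replicate 3. The lower count was 142, 186 and 121 without gu163 replicate 1, 2 and 3, and 234 without AF16 replicate 2, and it was 182 with only AF16 and gu163 in the fit and 555 by DESeq2. The split was 650 higher and 332 lower without AF16 replicate 3 and gu167 replicate 3 together.

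In gu167 larvae, germline genes again rose against AF16, and edgeR called few genes lower. Among the 50 germline and P granule genes, 19 rose and none fell (23 and 0 adjusted over the list alone; camera adjusted p = 2.28e-14, and adjusted p = 0.00959 with an estimated correlation). Cbr-egg-3 rose 33.4-fold (log2 5.06 ± 0.34, n = 3 per strain, edgeR adjusted p = 4.25e-05), Cbr-puf-8 by 3.70 ± 0.21, the synaptonemal complex gene Cbr-syp-1 by 4.54 ± 0.53 and the chondroitin proteoglycan gene Cbr-cpg-4 by 4.58 ± 0.52. Cbr-rme-2, chosen after its value was seen, rose by 3.14 ± 0.26 as the 1 of 4 yolk genes called over all genes. Adjusted over the list alone 3 yolk genes were higher and 0 lower, with a median log2 fold change of 3.39. Summed yolk protein transcripts (Cbr-vit-2, Cbr-vit-4 and Cbr-vit-6) stood at 308 CPM in gu167 replicate 3, against 46.7 and 12.5 CPM in the other gu167 libraries, 46.8 to 65.3 CPM in AF16 and 20.4 to 34.0 CPM in gu163. Of 7 sperm genes 2 rose (3 adjusted over the list alone; camera adjusted p = 0.0158, and adjusted p = 0.250 with an estimated correlation), a call lost without AF16 replicate 3 (0.0796). They were Cbr-spe-6 (2.61 ± 0.34) and the sperm ferlin gene Cbr-fer-1, whose ratio to 2 AF16 counts was 47.4 (95% interval 12.8 to 396).

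Of 30 small RNA pathway genes 4 rose in gu167 (7 adjusted over the list alone, with 0 lower; camera adjusted p = 6.32e-05, and adjusted p = 0.205 with an estimated correlation), led by Cbr-sago-2 (1.17 ± 0.11), Cbr-mut-2 (3.18 ± 0.40) and Cbr-prg-1 (1.66 ± 0.21). Of 47 DNA replication and cell cycle genes 4 rose (5 adjusted over the list alone; camera adjusted p = 0.00826, and adjusted p = 0.368 with an estimated correlation), including Cbr-orc-3 (0.74 ± 0.15) and the condensin gene Cbr-hcp-6 (0.90 ± 0.18), whose calls were lost in 5 and 3 of 6 fits without 1 library (adjusted p up to 0.121 and 0.138). This count was 1 without AF16 replicate 1, AF16 replicate 2 or gu167 replicate 1, and 0 without gu167 replicate 2 or 3. Cbr-cyp-31A3 rose by 4.72 ± 0.28 and the glucuronosyltransferase gene Cbr-ugt-63 by 1.47 ± 0.23, among 5 of 133 xenobiotic metabolism genes that rose (5 and 1 lower adjusted over the list alone). That count of 5 lay between 2 and 3 when any 1 library was left out, and without AF16 replicate 3 the list had 7 lower genes. Among well-measured called genes with or without a symbol, the largest rises were those of CBG02852, with a ratio of 103 to 2 AF16 counts (95% interval 28.3 to 858), and CBG08228 (6.14 ± 0.32). Cbr-glp-1 rose by 0.94 ± 0.18, lost without AF16 replicate 1 or 2 or gu167 replicate 2 or 3 (adjusted p up to 0.116). It was the only called gene of the Notch list (1 higher and 2 lower adjusted over the list alone), and Cbr-lin-3 the only one of the EGF and Ras list (1 and 0).

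The 16 genes that fell in gu167 included Cbr-cdr-2, of a cadmium-responsive gene family, which went from 63.6 ± 28.4 to 6.14 ± 0.742 CPM (log2 -3.38 ± 0.41, edgeR adjusted p = 0.00139). The hedgehog-related Cbr-grl-10 (-1.52 ± 0.23) and the patched-related Cbr-ptr-1 (-1.15 ± 0.24) were the 2 of 54 members of their list that fell (0 and 21 adjusted over the list alone; camera adjusted p = 2.03e-09, and adjusted p = 0.250 with an estimated correlation). The call of Cbr-ptr-1 was lost without AF16 replicate 1 or any 1 gu167 library (adjusted p up to 0.180). Cbr-daf-6, Cbr-madd-4 and CBG11275 also fell. Their calls passed in only 2, 1 and 2 of 6 fits without 1 library (adjusted p up to 0.183, 0.179 and 0.148). With only AF16 and gu167 in the fit these 3 calls were lost as well (edgeR adjusted p = 0.124, 0.0894 and 0.0573). The 30 molting genes had a median log2 fold change of -0.63 (camera adjusted p = 1.60e-06, and adjusted p = 0.250 with an estimated correlation). No molting gene passed over all genes, 7 were lower adjusted over the list alone, 15 at an unadjusted p under 0.05, and DESeq2 called 6. Values for Cbr-phy-2, a collagen prolyl hydroxylase gene, and Cbr-mlt-10 were -0.84 ± 0.20 and -1.91 ± 0.46.

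Further lists lay lower in gu167 by camera with 0 members called lower. Medians were -0.52 for 78 ribosomal protein genes (adjusted p = 6.49e-13), -0.37 for 33 proteasome genes (3.22e-08), -0.32 for 57 neuronal genes (0.000149) and -0.31 for 40 muscle genes (0.00105). They were -0.30 for 19 heat shock genes (0.00434), -0.30 for 33 respiratory chain genes (0.00448), -0.24 for 28 intestine genes (0.0150), -0.37 for 118 cuticle collagens (0.0236) and -0.19 for 18 heterochronic genes (0.0469). With an estimated correlation all these lists had adjusted p between 0.633 and 0.731, and adjusted over the list alone each had 0 lower genes (3 respiratory chain genes and 1 collagen were higher). At an unadjusted p under 0.05 the ribosomal, proteasome, neuronal, muscle, heat shock, intestine and heterochronic lists had 2, 8, 7, 2, 2, 2 and 1 lower genes, and DESeq2 called 0, 1, 3, 0, 0, 0 and 0. The collagen and respiratory chain lists had 28 and 2 lower and 11 and 3 higher genes at an unadjusted p under 0.05. DESeq2 called 10 and 1 lower and 6 and 3 higher. Within the respiratory chain list Cbr-nduf-2.2 (1.36 ± 0.19) and Cbr-sdha-2 (0.94) rose, the call of Cbr-sdha-2 being lost in 5 of 6 fits without 1 library (adjusted p up to 0.122), as did the collagen Cbr-col-83 (2.09 ± 0.38), a call lost without AF16 replicate 2 or gu167 replicate 2 (adjusted p up to 0.0883). Mean changes relative to other genes also moved within calls that held. Without AF16 replicate 3 the ribosomal mean went from -0.56 to -0.28 (adjusted p = 0.000300), and without AF16 replicate 3 and gu167 replicate 3 together the proteasome mean went from -0.38 to -0.18. Without AF16 replicate 1 and without gu167 replicate 1 the muscle mean went from -0.29 to -0.47 and -0.49, the intestine mean from -0.34 to -0.53 and -0.59, and the heat shock mean from -0.23 to -0.36 and -0.36. The respiratory chain mean went from -0.26 to -0.48 without gu167 replicate 1. Without AF16 replicate 3 the camera calls of the collagen (adjusted p = 0.121), heterochronic (0.996), muscle (0.246), neuronal (0.122), intestine (0.121), heat shock (0.0655) and respiratory chain (0.188) lists were lost. Several were also lost without another library: collagens without gu167 replicate 1 (0.0938), heterochronic and heat shock genes without gu167 replicate 2 (0.0630 each), and heterochronic (0.164), muscle (0.218), intestine (0.354) and respiratory chain genes (0.321) without gu167 replicate 3. The intestine call was lost without AF16 replicate 2 as well (0.146), and the ribosomal call without AF16 replicate 3 and gu167 replicate 3 together (0.265).

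No list of the remaining groups passed in gu167. The edgeR test called 2 of 76 innate immunity genes, led by Cbr-clec-147 (log2 3.81 ± 0.46), 1 of 44 chemoreceptor genes and 1 of 118 nuclear hormone receptor genes (2, 1 and 0 adjusted over the list alone). Chosen after their values were seen, the last 2 were Cbr-srsx-25 (5.61), which passed in 6 of 6 fits without 1 library, and Cbr-unc-55 (-2.11), lost in 4 of 6 (adjusted p up to 0.105). The EGF and Ras list and the innate immunity list had medians of -0.01 and means of 0.04 and 0.07, and camera placed the former higher and the latter lower, neither past the threshold. It called 0 of 29 Wnt, 0 of 26 synMuv, 0 of 10 presenilin suppressor, 0 of 18 H2A.Z deposition and 0 of 4 histone genes (0 in each adjusted over the list alone), against 3, 3, 4, 1 and 1 at an unadjusted p under 0.05 and 0, 1, 0, 0 and 0 by DESeq2. In all, 246 genes rose and 16 fell in gu167 (262 called, 1875 at an unadjusted p under 0.05), and DESeq2 called 396 and 204. The total was 152 without gu167 replicate 2 and 159 without gu167 replicate 3. The lower count was 145 without AF16 replicate 3, 85 without AF16 replicate 2, 8 without AF16 replicate 1, and 6, 4 and 2 without gu167 replicate 1, 2 and 3. It was 34 with no filter on low counts and 7 with only AF16 and gu167 in the fit. Without AF16 replicate 3 and gu167 replicate 3 together, 155 genes were higher and 69 lower. The calls of Cbr-ptr-1, Cbr-glp-1, Cbr-col-83, Cbr-sdha-2, Cbr-orc-3 and Cbr-hcp-6 were lost in that fit (adjusted p from 0.0512 to 0.139) and with only AF16 and gu167 in the fit (0.0546 to 0.0978). That of Cbr-orc-3 was also lost with no filter on low counts (0.0620) and that of Cbr-sdha-2 by limma-voom (0.0591).

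**Figure D3:**
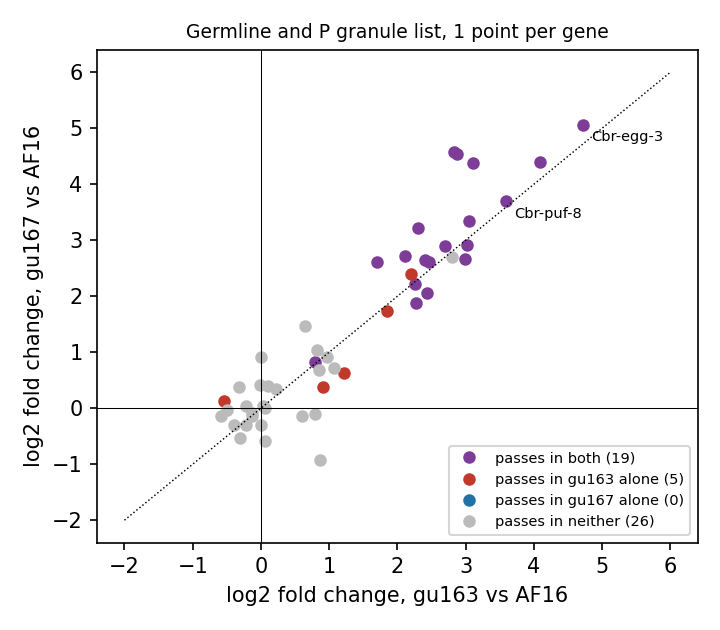
Log2 fold change against AF16 of 50 germline and P granule genes in gu163 (x axis) and gu167 (y axis), 1 point per gene, coloured by the strains in which edgeR's adjusted p passed 0.05; the dotted line marks equal values. The 19 genes that passed in both lie in the upper right, with Cbr-egg-3 at 4.72 and 5.06.

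Genes that rose in gu167 were largely among those that rose in gu163. Of the 246, 200 also rose in gu163, where 15.6 would be shared by independent lists of these sizes. The 5 genes with a symbol and the smallest adjusted p in both were Cbr-duo-2 (log2 3.66 ± 0.24 and 4.47 ± 0.24 in gu163 and gu167), Cbr-puf-8 (3.59 ± 0.21 and 3.70 ± 0.21), Cbr-cyp-31A3 (4.42 ± 0.28 and 4.72 ± 0.28), Cbr-egg-3 (4.72 ± 0.35 and 5.06 ± 0.34) and the anaphase-promoting complex gene Cbr-mat-3 (3.13 ± 0.20 and 2.81 ± 0.20). All 19 germline list members that rose in gu167 rose in gu163 as well. By the direct test, 32 of the 200 genes differed between the mutants. CBG01434, CBG06384 and CBG05663, chosen after their values were seen, fell in both, where 0.471 genes would be shared by independent lists. Their calls were lost in 0, 0 and 5 of 6 fits without 1 library in gu163 (adjusted p up to 0.165) and in 3, 4 and 5 of 6 in gu167 (adjusted p up to 0.114). The shared count was 0 without AF16 replicate 1, 30 without AF16 replicate 2 and 5 without AF16 replicate 3. CBG07747 fell in gu163 (-1.17 ± 0.32) and rose in gu167 (1.45 ± 0.29), where independent lists would share 7.24, and both calls were lost in most fits without 1 library (adjusted p up to 0.131 and 0.115) and with only the compared strains in the fit (0.125 and 0.0807). The gu163 call was also lost with upper-quartile scaling (0.0555) or limma-voom (0.0878), and the gu167 call without AF16 replicate 3 and gu167 replicate 3 together (0.130).

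Both comparisons used the same 3 AF16 libraries. In 50 simulations, all 9 libraries, AF16 included, were drawn gene by gene from AF16 mean levels with no change between strains. No gene rose in both and none fell in both, which was to be expected where nothing was changed. Deviations of whole AF16 libraries were not simulated, so the shared genes cannot be judged by these counts. Across genes, which are not independent replicates, the log2 fold changes of the mutants correlated at r = 0.44, below the 0.52 ± 0.013 (SD) of the simulations, and 59.7% had the same sign against 66.8% simulated. The covariance was 0.263, against 0.0735 simulated, a difference of 0.189. The controls are too few to split, so part of the excess of shared genes may come from them.

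Direct comparison of the mutants found hedgehog-related, molting and collagen genes lower in gu167 than in gu163. Of 54 hedgehog-related and patched-related genes, 28 were lower and 3 higher (33 and 4 adjusted over the list alone; camera adjusted p = 3.55e-08, and adjusted p = 0.402 with an estimated correlation). Cbr-grl-3, Cbr-grd-7 and Cbr-grl-10 had log2 differences of -5.58, -4.19 and -2.22 (edgeR adjusted p = 0.00228, 0.00500 and 0.000656). The 28 were 17 without gu163 replicate 1 or gu167 replicate 3, and 18 without gu167 replicate 2. The 3 higher members became 0 without gu163 replicate 1, gu167 replicate 2 or gu167 replicate 3, and 1 without gu163 replicate 2 or 3. Of 30 molting genes 15 were lower (16 lower and 1 higher adjusted over the list alone; camera adjusted p = 1.64e-05, and adjusted p = 0.402 with an estimated correlation), including Cbr-acn-1 (-1.88) and Cbr-mlt-10 (-1.80). This count was 6 without gu163 replicate 1 or gu167 replicate 3, 8 without gu163 replicate 3 and 7 without gu167 replicate 2. Of 118 collagens 40 were lower and 3 higher (63 and 9 adjusted over the list alone; camera adjusted p = 5.42e-07, and adjusted p = 0.802 with an estimated correlation). Cbr-col-158 differed by -10.48 ± 1.28 and Cbr-col-36 by -7.49, and Cbr-col-45 had 1 count over the gu167 libraries, a ratio of 2236 in favour of gu163 (95% interval 401 to 88344), a call lost by limma-voom (adjusted p = 0.0609). The 40 were 26 without gu163 replicate 1 and 25 without gu167 replicate 3, and the 3 higher were 5 without gu167 replicate 1 and 1 without gu167 replicate 3.

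**Figure D4:**
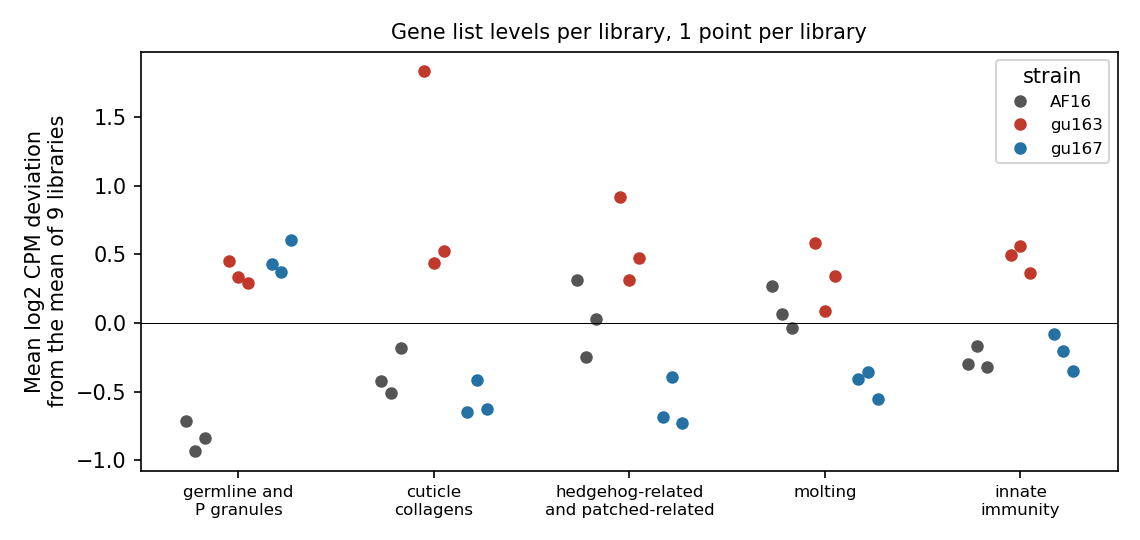
Mean log2 CPM of 5 gene lists in each library, as deviation from the mean of the 9 libraries (y axis), with 1 point per library coloured by strain. Germline levels lie above 0 in all mutant libraries and below 0 in AF16, and the collagen mean reaches 1.84 in gu163 replicate 1.

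Innate immunity genes were also lower in gu167 than in gu163, with 23 of 76 lower and 3 higher (26 and 4 adjusted over the list alone; camera adjusted p = 0.000420, and adjusted p = 0.402 with an estimated correlation). Cbr-clec-147, Cbr-clec-86 and Cbr-clec-78 differed by log2 -3.08, -3.81 and -6.06, and Cbr-clec-186 by 2.38 ± 0.33 in the other direction. The 23 were 15 without gu167 replicate 2, and the 3 higher were 1 without gu163 replicate 1, gu167 replicate 1 or gu167 replicate 2. Of 47 DNA replication and cell cycle genes 7 were lower (7 adjusted over the list alone; camera adjusted p = 0.00107, and adjusted p = 0.402 with an estimated correlation), a count that lay between 0 and 2 when any 1 gu163 or gu167 library was left out. Proteasome genes had a median of -0.37 with 1 of 33 lower (0 adjusted over the list alone; camera adjusted p = 5.61e-06, and adjusted p = 0.864 with an estimated correlation). Their mean relative to other genes moved from -0.31 to -0.16 without gu163 replicate 1 and to -0.18 without gu167 replicate 3. Nuclear hormone receptor genes had a median of 0.20 with 3 of 118 higher and 2 lower (1 and 0 adjusted over the list alone; camera adjusted p = 0.0189, and adjusted p = 0.914 with an estimated correlation), a call lost without gu163 replicate 1 (0.217) or gu167 replicate 3 (0.112). These counts of 3 and 2 were 1 and 0 without gu163 replicate 1, gu163 replicate 3, gu167 replicate 1 or gu167 replicate 3, 1 and 1 without gu167 replicate 2, and 3 and 1 without gu163 replicate 2. Cbr-cyp-14A1 (3.19 ± 0.59) and the sulfatase gene Cbr-sul-3 (2.34 ± 0.34) were higher in gu167. Cbr-spr-4 was lower in gu167 than in gu163 by the direct test (-0.65 ± 0.16, adjusted p = 0.0264), a call lost in 5 of 6 fits without 1 library (adjusted p up to 0.0966) and without AF16 replicate 3 and gu167 replicate 3 together (0.0508). Among 50 germline genes, 4 were higher and 1 lower in gu167 than in gu163 (4 and 1 adjusted over the list alone) and the list did not pass (camera adjusted p = 0.426). These counts were 0 and 0 without gu163 replicate 1 or gu167 replicate 2, 2 and 1 without gu163 replicate 2, 1 and 1 without gu163 replicate 3, 3 and 0 without gu167 replicate 1, and 2 and 0 without gu167 replicate 3. In all, 641 genes were higher and 1042 lower in gu167 (1683 called, 3555 at an unadjusted p under 0.05). The total was 710 without gu163 replicate 1, 883 without gu163 replicate 3, 1082 without gu167 replicate 1, 758 without gu167 replicate 2 and 757 without gu167 replicate 3. The higher count was 190, 425 and 269 without gu163 replicate 1, 2 and 3, and 382, 239 and 286 without gu167 replicate 1, 2 and 3. The lower count was 520, 839 and 614, and 700, 519 and 471, in the same order.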

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

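The tests of explanations and the counts over other splits of the libraries were chosen after the results were seen, whereas the direct comparison of the mutants and the fits without single libraries were planned.

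Germline genes rose in both mutants. Adult animals among the larvae, which hold yolk protein transcripts in abundance, stay open for gu163: summed yolk protein CPM (22.8, 34.0 and 20.4) lay below every AF16 library (46.8, 63.8 and 65.3) in 3 of 3 libraries, but most of it was Cbr-vit-6, which was high in AF16 too, and Cbr-vit-2 and Cbr-vit-4 together (0.521, 6.38 and 0.805) lay above every AF16 library (0.504, 0.348 and 6.17) in gu163 replicate 2. They stay open for gu167 too, since the highest gu167 library held 307.9 CPM of these transcripts, the others 46.7 and 12.5, and Cbr-vit-2 and Cbr-vit-4 alone lay above every AF16 library in 2 gu167 libraries. A single AF16 library as the cause is argued against because at least 16 germline list members were called in each mutant without any 1 of them. A later developmental time of the mutant animals cannot be told apart from an effect of genotype, because molting genes rise and fall within each stage and differed between the mutants (-0.70 in mean log2 against other genes), and late larvae or young adults without yolk stay open for both.

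Hedgehog-related and patched-related genes were lower in gu167 than in gu163. The difference does not rest on gu163 replicate 1 alone, since 17 members were still lower without it, against 28 with it. In 3 of 3 gu167 libraries the mean level of the list (-0.68, -0.39 and -0.72) lay below every AF16 and gu163 library. Different times in the molt cycle would give this as well as a change by genotype would, so these cannot be told apart here. For the molting genes and the collagens, including the collagen rises in gu163, times in the molt cycle were not separated from genotype either.

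Few genes were called lower by edgeR in gu167 than in AF16, 16 against 246 higher. DESeq2 on the same libraries called 204 lower and 396 higher, so the small count depends on the test used. Normalization as the cause stays open: RLE and upper-quartile scaling called 17 and 11 lower genes, but they moved the median of all genes by -0.0073 and 0.07, so these settings do not decide it. Without AF16 replicate 3 the lower count was 145, which is consistent with this library widening the spread, and it was 85 without AF16 replicate 2 and 8 without AF16 replicate 1. The count of 85 leaves open that AF16 replicate 3 is not the only library involved.

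For each comparison, 1 of the 10 splits of the 6 libraries into 3 and 3, the real one, gave as many called genes. The real splits called 1163 (gu163 against AF16), 262 (gu167 against AF16) and 1683 genes (gu167 against gu163), and the highest other split called 0 in each. At an unadjusted p under 0.05 the real splits had 2955, 1875 and 3555 genes and the highest other splits 1326, 1737 and 572. The other splits mixed the strains within each group, so strain differences widened the spread there and few calls were expected. Their count of 0 therefore decides nothing about the cause. The 10 splits are too few for a share under 0.05.

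Changes against AF16 differed between the strains, by the direct edgeR or camera test, for 7 lists and for the following named genes. Differences are gu167 minus gu163 on the log2 scale. Some gene calls lay near the threshold, with edgeR adjusted p up to 0.0479 (Cbr-hsp-60). In this comparison 7 of the named genes were refitted without 1 library, of which 6 passed in every fit and Cbr-spr-4 did not. Against AF16, 13 of 59 named calls in gu163 and 13 of 33 in gu167 were lost in at least 1 such fit. The other gene calls between the mutants were not refitted in this way. List medians were -1.28 for collagens, -1.03 for molting, -1.34 for hedgehog-related, -0.23 for innate immunity, -0.24 for DNA replication, -0.37 for proteasome and 0.20 for nuclear hormone receptor genes. With an estimated correlation none of these 7 lists passed (camera adjusted p from 0.402 to 0.914). Collagens differed by -10.48 (Cbr-col-158), -9.08 (Cbr-col-114), -9.04 (Cbr-col-102), -7.49 (Cbr-col-36), -3.02 (Cbr-col-71), 1.73 (Cbr-col-39) and 2.24 (Cbr-col-86). Fitted values of -10.78 (Cbr-col-163), -10.92 (Cbr-col-45) and -5.99 (Cbr-col-85) rest on few counts in a strain and are no bounds.

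Among cuticle-linked and signalling genes the differences were -5.58 (Cbr-grl-3), -4.19 (Cbr-grd-7), -2.65 (Cbr-ptr-19), -2.22 (Cbr-grl-10), -1.73 (Cbr-ptr-1), -1.50 (Cbr-daf-6), -1.85 (Cbr-wrt-1), -1.40 (Cbr-phy-2), -1.80 (Cbr-mlt-10), -1.88 (Cbr-acn-1), -1.10 (Cbr-dsl-3) and 0.86 (Cbr-lin-7). Innate immunity and metabolism genes gave -3.08 (Cbr-clec-147), -3.81 (Cbr-clec-86), -6.06 (Cbr-clec-78), 2.38 (Cbr-clec-186), 3.19 (Cbr-cyp-14A1), 1.96 (Cbr-ddo-1), 2.34 (Cbr-sul-3), -1.37 (Cbr-dhs-11), 1.22 (Cbr-pgp-9) and -2.89 (Cbr-cdr-2). Genes of the intestine list gave -1.67 (Cbr-cpr-6) and -1.17 (Cbr-cpr-4). Heat shock genes gave -3.40 (Cbr-hsp-70), 1.09 (Cbr-hsp-6), 0.80 (Cbr-hsp-60) and -0.84 (Cbr-hsp-4). Germline and sperm genes gave 1.75 (Cbr-cpg-4), 1.67 (Cbr-syp-1), 2.28 (Cbr-fer-1), -3.68 (Cbr-spe-41) and -5.43 (Cbr-spe-27). Other genes gave 0.81 (Cbr-duo-2), -2.27 (Cbr-flp-1), -2.80 (Cbr-cat-2), -0.71 (Cbr-madd-4), -0.57 (Cbr-mlc-4), 0.57 (Cbr-rpl-24.2), -2.32 (Cbr-rpl-11.1), -0.48 (Cbr-mcm-6), -0.51 (Cbr-rpn-3), 0.78 (Cbr-nhr-31), -0.65 (Cbr-spr-4), 4.13 (CBG13822), 1.61 (CBG12124), 1.11 (CBG08228), -2.62 (CBG11275) and 2.62 (CBG07747).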

How the results depend on the processing

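The fits without AF16 replicate 3 and gu167 replicate 3 together were chosen after the data were seen, and all other alternatives were planned. Of 2191 fits of named genes under alternatives, 1893 kept direction and side of the threshold, 267 lost the call, 29 gained it and 2 reversed, and of 429 list tests 335 kept both, 91 lost the call and 3 reversed. Gene counts stayed within 1.5 times in 33 of 51 alternatives. With 2-group fits 759 genes changed in gu163 and 169 in gu167, but 2290 between mutants (905 higher and 1385 lower), and Cbr-lin-3 in gu167 (2.12) no longer passed (adjusted p = 0.0698). DESeq2 called 600 genes in gu167, including 260 of the 262, and 13 lower in both mutants. At adjusted p under 0.0005, the literal reading of the submitters' printed FDR, the counts were 85 (gu163), 42 (gu167) and 25 (between mutants). Of these genes 33 were higher in both mutants and 0 lower in both. Cbr-lin-3 (2.49 and 2.12) and Cbr-spr-4 (1.12) did not pass that stricter threshold. Requiring a 2-fold change left 755 genes in gu163 and 969 between mutants. With an estimated correlation 1, 1 and 0 lists passed for gu163, gu167 and between mutants, and with fry 5, 4 and 4. Without 1 library at a time, gene counts were 654 to 1078 (gu163), 152 to 367 (gu167), 710 to 1264 (between mutants) and 0 to 30 (lower in both), list calls 9 to 17 (gu167) and 7 to 11 (between mutants), and Cbr-lin-3 in gu167 1.72 to 2.35. Cbr-htz-1 in gu167, not called in any fit reported here, ranged from -0.22 to 0.0014, and the neuronal list in gu163 from -0.38 to 0.0011 relative to other genes, each changing sign without AF16 replicate 3. Without AF16 replicate 3 and gu167 replicate 3 together, 8 lists passed in gu167, Cbr-lin-3 was at 2.39 (adjusted p = 0.0599), Cbr-htz-1 at 0.041, and the muscle and respiratory chain lists turned to 0.11 and 0.029 relative to other genes. Deviations of same-numbered libraries correlated with mixed signs, at -0.29, 0.19 and -0.16 (AF16 and gu163), -0.28, -0.07 and -0.24 (AF16 and gu167) and 0.23, -0.08 and 0.25 (the mutants). Differently numbered libraries were not compared, so these values do not settle whether replicate numbers pair the libraries. With replicate number as a block, 876, 173 and 1240 genes were called, 846, 166 and 1186 of them shared with the fit without it, and Cbr-lin-3 in gu167 was at 2.10 (adjusted p = 0.0740). The edgeR call of Cbr-spr-4 between the mutants was also lost with this block (-0.64, adjusted p = 0.0588). Another strand column was not run, as 1 count column was used per library. Where no cause is named above, the cause was not tested. Depth of 8294524 to 14095189 counts limits genes such as Cbr-lin-3, with 3 to 7 counts per AF16 library.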

Other observations

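All tests in this part were chosen after the data were seen.

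Genes of the mitochondrial ribosome were lower in gu163. In a screen of 69 gene families named by symbol (414 Fisher tests, which treat genes as independent), 10 tests passed after Benjamini-Hochberg adjustment. The genes of mitochondrial ribosomal proteins (mrpl and mrps) were in no list fixed in advance. They were picked after the genes that fell in gu163 were seen, and were joined as 1 family for the screen. By edgeR 36 of 62 fell in gu163, with a median log2 fold change of -0.63 and 62 of 62 below 0. In gu167 edgeR called 0 of them (1 at an unadjusted p under 0.05, 0 by DESeq2; median 0.03), and 43 were higher in gu167 than in gu163. The count of 43 uses the same gu163 libraries for which the family was picked, so it is no separate support. The mean deviation of the family was -0.39, -0.42 and -0.39 in the gu163 libraries, 0.29, 0.17 and 0.09 in AF16 and 0.40, 0.16 and 0.10 in gu167. Another family outside those lists was ttr (transthyretin-like), of which 9 of 37 genes were higher in gu167 than in gu163 (adjusted p = 0.00133). The 36 became 18, 19 and 38 without AF16 replicate 1, 2 and 3, and 18, 14 and 14 without gu163 replicate 1, 2 and 3. In these fits the median log2 fold change of the mitochondrial family lay between -0.64 and -0.54. A hypothesis is that these genes may fall together in gu163: camera with an estimated correlation gave p = 0.0318, which decides nothing because the family was picked for its fall.

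In the gene order of assembly CB4, genes called in the same direction lay next to each other more than in random sets in the 5 sets tested, which leave out the genes that fell in gu167 against AF16. Of 794 genes that rose in gu163 and had a position, 242 (30.5%) neighboured another, against a mean of 65.1 and a maximum of 97 in 2000 random sets matched on level (permutation p = 0.0005, the smallest these sets can give). Of those that fell in gu163 it was 46 of 368 (12.5%, mean 17.2, maximum 37), and of those that rose in gu167 89 of 246 (mean 6.34, maximum 24). Between the mutants it was 122 of 641 higher in gu167 (mean 48.4, maximum 84) and 238 of 1041 lower (mean 118, maximum 168), with the same permutation p in each set. There were 27 runs of at least 3 genes that rose in gu163, with 94 genes in all. Neighbouring genes changing together is consistent with these counts as a hypothesis, but operons, tandem gene families and reads shared by overlapping genes, whose strand cannot be told apart here, were not separated.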
